A study of Dunaliella salina with 9 samples.

How the data were processed

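RNA was extracted with Trizol reagent from Dunaliella salina cells, and 1.5 µg per sample was made into libraries with the NEBNext Ultra kit for Illumina sequencing, per the labels' protocols. The cells were collected in mid-exponential growth and put into fresh medium for the light treatment. The time between the change of irradiance and the harvest is not given in the sources used here. The growth phase label of all 9 samples holds the word 7th beside the phase, without a unit, and was not interpreted. Groups were taken from the sample titles and irradiance labels, with 3 libraries each at 150 (LL), 600 (ML) and 1500 µmol photons m⁻² s⁻¹ (HL).

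The authors deposited 1 table per library with a read count and an FPKM value (fragments per kilobase, scaled to depth) for each of 76875 clusters, per the file headers. Per the file headers and their values, the authors deposited estimated counts, not normalized to depth or length, that carry decimals. Of the clusters in a library, 27.9% to 31.0% had a non-whole value. Such values can arise when a counting program divides a read among similar sequences. The FPKM values were divided by the authors by length and depth, per the file headers. The submitters' processing notes name DESeq 1.10.1. The assembler, aligner, counter, annotation and reference build are not given in the sources used here, and neither is the meaning of the numbers that make up a cluster identifier. The leading number was 5009 for 61470 of the 76875 listed clusters and for 33989 of the 34377 tested, the 4 named ones included. Whether these are similar sequences of a common group is not known, so clusters may not all be separate transcripts. Where reads were divided in this way, the level of a single cluster is uncertain, and an abundant cluster can lend counts to a rarer one.

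None of the cluster identifiers matched a locus tag, gene identifier or accession in the gene table of the Dunsal1 v.2 assembly (0 of 76875), and the files do not pair the identifiers with gene names. The tests of gene lists for photosynthesis, pigment synthesis, antioxidants, central metabolism and cell division that had been fixed in advance were therefore not run. Neither were the lists for bacteria, organelles and ribosomal RNA. No coordinates are given for the same reason.

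Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Clusters were kept with edgeR's default expression filter, which left 34377 clusters holding 99.4% to 99.7% of the counts of each library, while 3772 clusters had no count in any library. TMM factors were used, and their mean was 1.03 in LL, 1.06 in ML and 0.918 in HL. A robust quasi-likelihood model with group as the only term was fitted to all 9 libraries, which share an estimate of the spread, and gave 6 residual degrees of freedom and a common biological coefficient of variation of 0.276. HL was compared with LL, ML with LL and HL with ML, and the 3 groups were compared jointly. P-values were adjusted by Benjamini-Hochberg within each test, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic.

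With 3 libraries per group, differences of library-level values were tested with exact two-sided permutation tests, for which 0.1 is the smallest p possible. Of the 10 library-level measures compared in 30 tests, 0.143 was the smallest Benjamini-Hochberg adjusted p. Read shares by abundance and length were tested in the same way in another 30 tests, with a smallest adjusted p of 0.130. Library totals ranged from 17778225 to 19643714 counts, and numbers of detected clusters were compared after thinning each library to 17778144 counts. The 95% intervals of shares and ratios of clusters treat clusters as independent, which they are not, and do not cover the spread between libraries. Libraries were compared with each other before averaging: within groups the chi-square per degree of freedom was 7.31 to 12.9, so that no pair had the near-identical counts of a library deposited more than once. This does not tell separate cultures from separate preparations.

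The length of a cluster was derived from the ratio of its count to its FPKM at an FPKM of at least 0.5, and was available for 98.5% of the tested clusters, with a median of 1074 bases. Among 8058 well-measured clusters this length varied between libraries with a median coefficient of variation of 0.465%. Quintiles of abundance were taken over all 9 libraries. Principal components were computed from log2 CPM with a prior count of 2.

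Named clusters followed a rule for files without gene names, fixed before the data were examined: for HL against LL, the 2 rising and the 2 falling clusters with the smallest p among those with a mean CPM of at least 10, with their values in ML. Overlaps with LL as a shared control were set beside 20 simulated sets of unchanged groups, drawn around the observed LL means, and beside the overlap of independent lists.

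Counts for HL against LL were simulated over 34377 clusters, with 100 clusters changed at each fold, all of an average abundance of at least 10 CPM. There, edgeR recovered 94% of the 2-fold and 95% of the 4-fold changes with 13 false calls. Recovery of rarer clusters was not measured. Alternatives were DESeq2 1.42.0, limma 3.58.1 with voom or on log2(FPKM + 1) and log2(FPKM + 0.1), RLE, upper-quartile and library-total scaling, other filters and fold thresholds, the compared libraries alone, a replicate block and leaving out each library. Clusters with whole counts in all 9 libraries, and offsets that remove each library's trend on abundance and length, were added as alternatives after seeing the data, as were the alternatives for overlaps.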

Results

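Transcript abundance was measured by RNA sequencing in Dunaliella salina, a unicellular green alga of saline waters that is known for building up carotenoids and glycerol. Cells had been grown at 22 °C and 150 µmol photons m⁻² s⁻¹ under 16 h of light and 8 h of dark, and the irradiance was then raised in a single step. The 9 libraries fell into 3 groups of 3, named here LL for cells kept at 150, ML for cells moved to 600 and HL for cells moved to 1500 µmol photons m⁻² s⁻¹. Per the series title, the question was how gene expression changes while the alga acclimates to high irradiance. The files list 76875 transcript clusters by number and do not pair them with gene names, so the clusters are described here by their response, abundance and length, and only 4 are given by identifier. Library totals were 17778225 to 18914255 counts in LL, 18451243 to 19535140 in ML and 18799637 to 19643714 in HL. Although the series design calls the samples biological, no label says that they came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

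The libraries separated by irradiance, with LL between the groups moved to higher light. On the leading principal component, which held 43.5% of the variance over 34377 clusters, the ML libraries lay at −125 to −109, the LL libraries at −21.6 to −13.3 and the HL libraries at 131 to 143. The second component, with 16.6% of the variance, placed LL at 86.5 to 98.7 and both other groups at −59.2 to −32.9. Pearson correlations of log2 abundance across clusters were 0.934 to 0.938 between libraries of a group. They were 0.885 to 0.896 between LL and ML, 0.874 to 0.880 between LL and HL, and 0.811 to 0.832 between ML and HL.

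**Figure D1:**
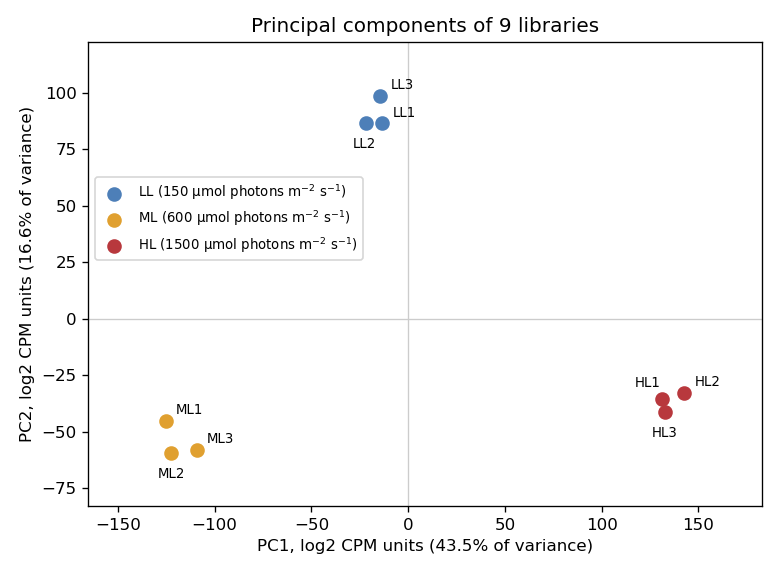
Principal component scores of the 9 libraries on the log2 CPM scale, with PC1 (43.5% of the variance) on the horizontal axis and PC2 (16.6%) on the vertical axis; each point is a library, coloured by irradiance group. The ML and HL libraries lie at opposite ends of PC1, from −125 to −109 and from 131 to 143, and the LL libraries lie between them.

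A large part of the transcriptome differed between cells moved to 1500 µmol photons m⁻² s⁻¹ and cells kept at 150. Of the 34377 clusters tested, 15317 (44.6%) differed between HL and LL, of which 7608 were higher and 7709 lower in HL. Most of these changes were moderate, with a median absolute log2 fold change of 0.85. At least 2-fold changes were seen for 2655 higher and 3467 lower clusters, and at least 8-fold changes for 311 and 309. The calls are from edgeR's quasi-likelihood F-test at a Benjamini-Hochberg adjusted p below 0.05. The balance of directions depended on the scaling: with library totals alone, which moved the median log2 fold change of all clusters from 0.01 to −0.15, 36.1% of the called clusters were higher in HL, against 49.7% with the scaling used throughout. On the deposited FPKM values this share was 36.7% with a pseudocount of 1 and 35.2% with 0.1. It went the other way with RLE factors, to 51.7%, and with DESeq2, to 51.3%.

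The most abundant transcripts rose at 1500 µmol photons m⁻² s⁻¹. Among the 100 clusters with the highest mean abundance, 71 were higher and 8 lower in HL than in LL, with a median log2 fold change of 0.38. With library totals alone 59 were higher and 14 lower, with a median of 0.21, and with each library's trend on abundance and length removed 55 and 19, with a median of 0.11. The 100 most abundant clusters of each library took 30.6% ± 0.47 of the counts in HL and 25.4% ± 0.91 in LL (SD, n = 3 each). All 3 HL libraries lay above all 3 LL libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Across the 5 quintiles of mean abundance, the median log2 fold change lay within 0.05 of 0, and with library totals alone between −0.17 and −0.12.

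Short and long clusters moved apart in HL. Of 7518 clusters with an implied length below 500 bases, 2066 were higher and 1091 lower in HL than in LL. Of 4417 clusters of at least 2500 bases, 578 were higher and 1423 lower. The long clusters held 18.1% ± 0.20 of the tested counts in HL and 19.7% ± 0.68 in LL (SD, n = 3 each, exact two-sided permutation p = 0.1). Library totals alone gave 1538 higher and 1407 lower short clusters, and 375 higher and 1723 lower long clusters. Removing each library's trend on abundance and length takes such shifts out by construction. With it removed, 1800 short clusters were higher and 1238 lower, and 914 and 1058 of the long clusters, whose median log2 fold change moved from −0.21 to 0.02. A length-dependent shift of whole libraries can also come from RNA integrity or library preparation, for which no measurement was used here.

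The 4 clusters given by identifier were those with the smallest p for HL against LL, 2 in each direction, so that their large differences follow from the choice. Cluster-5009.33224 rose from 123 ± 4.85 CPM (depth-scaled counts) in LL to 1299 ± 24.8 in HL (SD, n = 3 each), a log2 fold change of 3.40 with a standard error of 0.04 and an adjusted p of 4.79e-09 by edgeR's quasi-likelihood test. It stood at 681 ± 15.7 CPM in ML, so that it increased with irradiance at both steps (log2 fold change 2.47 from LL to ML and 0.93 from ML to HL). Cluster-5009.33827 rose from 162 ± 7.89 to 1015 ± 32.4 CPM (log2 2.64, SE 0.05, adjusted p = 5.44e-08) and was higher still in ML, at 1218 ± 33.4 CPM. The drop of this cluster from ML to HL was small, with a log2 fold change of −0.26 (SE 0.05, edgeR adjusted p = 0.00111). Its size depended on the processing, at −0.47 with library totals alone and −0.22 with DESeq2.

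Cluster-5009.54808 fell from 106 ± 4.19 CPM in LL to 46.1 ± 2.77 in ML and 10.5 ± 0.75 in HL (SD, n = 3 each). Its log2 fold change from LL to HL was −3.34 (SE 0.07, edgeR adjusted p = 8.16e-08). Cluster-5009.26724 fell from 28.8 ± 0.39 CPM to 16.0 ± 0.77 and 2.89 ± 0.32, a log2 fold change of −3.32 from LL to HL (SE 0.09, edgeR adjusted p = 1.90e-07). All 3 libraries of HL lay outside the LL range for each of the 4 clusters. Counts of Cluster-5009.33224 were whole numbers in all 9 libraries. The other 3 held non-whole counts in all 9, which can arise where reads are divided among similar sequences, so their levels may be less certain.

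**Figure D2:**
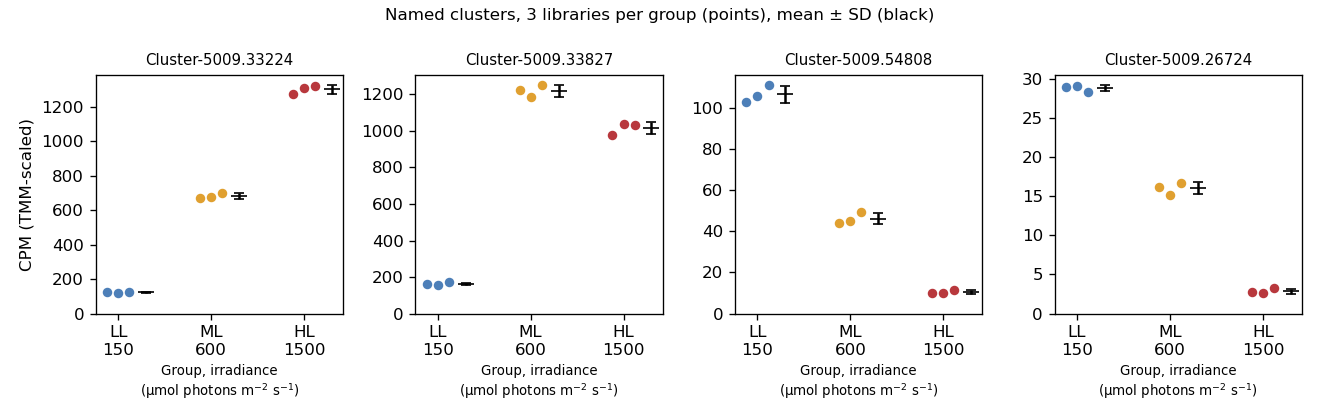
Abundance of the 4 named clusters in CPM (TMM-scaled) on the vertical axes, which start at 0 and differ in range, against irradiance group; coloured points are single libraries and black bars are the mean ± SD of 3. Cluster-5009.33224 rises from 123 to 681 and 1299 CPM, Cluster-5009.33827 peaks at 1218 CPM in ML, and Cluster-5009.54808 and Cluster-5009.26724 fall at each step.

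Moving cells to 600 µmol photons m⁻² s⁻¹ changed fewer clusters, and the abundant ones mostly fell. Of the 34377 clusters, 12587 (36.6%) differed between ML and LL in edgeR's quasi-likelihood test, with 5877 higher and 6710 lower in ML and a median absolute log2 fold change of 0.73. The balance of directions depended on the scaling, with 6182 higher and 6112 lower for library totals alone, and 6228 and 6229 for upper-quartile factors. On the FPKM values, where tool and filter also differ, it depended on the pseudocount. Limma gave 6869 higher and 6392 lower with a pseudocount of 1, and 5972 and 6274 with 0.1. Larger changes were mostly rises, since 2782 clusters were at least 2-fold higher and 1382 at least 2-fold lower, and 247 and 147 changed at least 8-fold. The excess was smaller in edgeR's test against a 1.5-fold minimum, with 2033 higher and 1454 lower. The limit set by the expression filter, given below for rare clusters, may apply to these counts too. Among the 100 clusters with the highest mean abundance, 13 were higher and 82 lower in ML. Their median log2 fold change was −0.41, and −0.26 with each library's trend on abundance and length removed (13 higher and 77 lower). The 100 most abundant clusters of each library took 22.3% ± 0.63 of the counts in ML, below the 25.4% ± 0.91 in LL (SD, n = 3 each, exact two-sided permutation p = 0.1).

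Rare clusters among those tested went the other way in ML. In the lowest quintile of mean abundance, 471 clusters were higher and 118 lower in ML than in LL, and in the highest quintile 1635 were higher and 3233 lower. The median log2 fold change went from 0.37 and 0.27 in the lowest 2 quintiles through 0.09 to −0.12 and −0.17 in the highest 2, and each sign was the same under RLE, upper-quartile and library-total scaling. The lowest quintile held 0.498% ± 0.035 of the tested counts in ML and 0.366% ± 0.017 in LL (SD, n = 3 each, exact two-sided permutation p = 0.1). Its clusters lay near the expression filter (median mean CPM 0.58), which the libraries of a single group can pass alone. More clusters were detected in ML, so part of the ML excess here may come from the filter, which other scalings do not address. Clusters of at least 2500 bases went up more often than down, 1023 against 738, and held 21.9% ± 0.58 of the counts in ML against 19.7% ± 0.68 in LL. With each library's trend on abundance and length removed, an alternative that takes such shifts out by construction, 210 clusters of the lowest quintile were higher and 234 lower, and 825 and 886 of the long clusters.

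**Figure D3:**
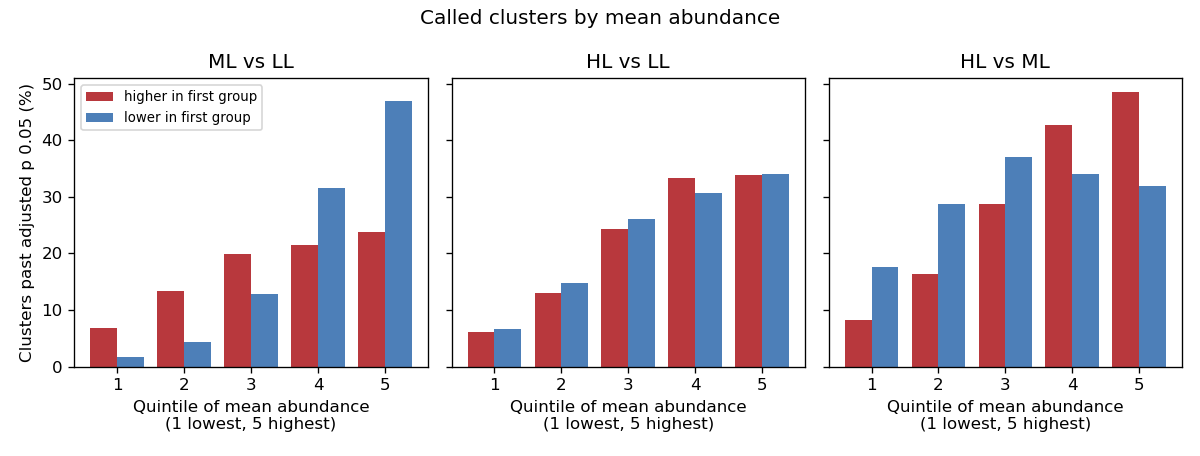
Share of clusters past an adjusted p of 0.05 (percent, vertical axis, starting at 0) in each quintile of mean abundance (horizontal axis, 1 lowest and 5 highest) for the 3 comparisons; red bars are clusters higher and blue bars clusters lower in the group named before "vs". In ML vs LL the lowest quintile is mostly higher (6.85% against 1.72%) and the highest mostly lower (23.8% against 47.0%); in HL vs ML the highest quintile has 48.5% higher and 32.0% lower, an excess that turns with library totals alone (2524 higher and 2891 lower clusters).

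The groups moved to higher light differed more from each other than either did from LL. Between HL and ML, 20219 clusters (58.8%) passed edgeR's quasi-likelihood test, 9935 higher and 10284 lower in HL, with a median absolute log2 fold change of 1.18. At least 2-fold changes were seen for 4911 higher and 6973 lower clusters, and at least 8-fold changes for 604 and 548. Among the 100 clusters with the highest mean abundance, 88 were higher and 8 lower in HL, and 85 and 12 with library totals alone. Long clusters of at least 2500 bases were more often lower in HL, 1689 against 798 higher. With each library's trend on abundance and length removed, which takes such shifts out by construction, 1247 were higher and 1215 lower.

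By abundance, the median log2 fold change from ML to HL rose from −0.48 in the lowest quintile to 0.14 and 0.17 in the highest 2, where it turned to −0.07 and −0.04 with library totals alone. In the lowest quintile 571 clusters were higher and 1208 lower. With each library's trend on abundance and length removed, again by construction without such shifts, these turned to 898 and 624, with a median of 0.10. The limit set by the expression filter, given for ML against LL, applies to this quintile too. Short clusters below 500 bases were more often higher in HL, 2486 against 1930, but with library totals alone 2084 were higher and 2297 lower. With library totals alone, 39.1% of the called clusters were higher in HL, against 49.1% with the scaling used throughout, and the median log2 fold change of all clusters moved from −0.07 to −0.28. On the FPKM values this share was 38.9%, while RLE factors gave 50.4% and DESeq2 50.1%.

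In the joint test of the 3 groups, 21424 clusters (62.3%) differed at some irradiance, and for most of these the mean in LL lay between the others. LL was in the middle for 13744 clusters (64.2%), ML for 4017 (18.8%) and HL for 3663 (17.1%). The most frequent orders were ML below LL below HL, with 6999 clusters, and HL below LL below ML, with 6745. A graded response, with a change in the same direction from LL to ML and from ML to HL that passed both edgeR tests, was found for 700 clusters, 318 rising and 382 falling. Independent lists of these sizes would share 1698 and 2007. The LL-to-ML and ML-to-HL comparisons share the ML libraries with opposite sign, which lowers such an overlap, so the shortfall is not a measure of effect. With another group in the middle, 854 clusters passed both neighbouring tests in the same way for HL and 4888 for LL.

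Clusters called at both raised irradiances more often went in opposite directions than in the same one. Of the clusters past the threshold against LL in both comparisons, 4888 had opposite signs and 2963 the same sign, so that 62.3% were opposite (exact 95% binomial interval 61.2 to 63.3, over clusters, which are not independent replicates). Among the opposite ones, 2732 were lower in ML and higher in HL, and 2156 were higher in ML and lower in HL. Independent lists would share 1485 and 1318. All 4888 also differed between HL and ML, which calls on opposite sides of LL all but fix. Of the others, 1520 were higher at both irradiances and 1443 lower at both, against 1301 and 1505 for independent lists.

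The comparisons with LL share its 3 libraries, which by chance alone favours calls in the same direction. In 20 simulated sets, unchanged groups were drawn around the observed LL means and compared with the same LL libraries. No cluster was called in both comparisons. Drawing around these means cancels the sampling error of LL, so the simulated values do not measure what the shared libraries add. The covariance of the log2 fold changes was 0.313 over all clusters, and 0.0394 in the simulated sets. Pearson's r across clusters was 0.19, and 0.127 (0.0963 to 0.157) in the simulated sets. The covariance was below 0 in parts of the data: −0.066 in the upper 2 abundance quintiles, against 0.0039 simulated, and −0.030 in clusters with whole counts in all 9 libraries, against 0.0026. The 3 LL libraries could not be divided into sets of at least 2, so part of any same-direction excess may come from the shared libraries.

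**Figure D4:**
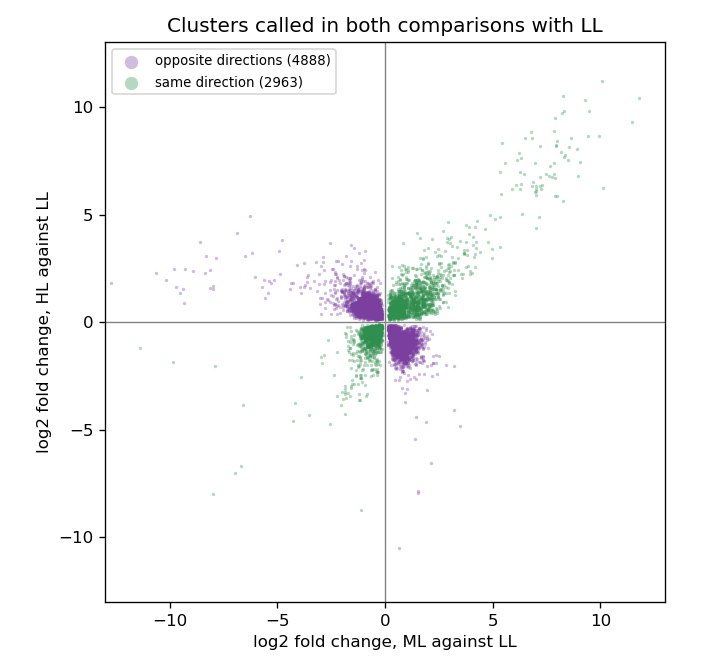
Log2 fold changes of the clusters past an adjusted p of 0.05 in both comparisons with LL, ML against LL on the horizontal axis and HL against LL on the vertical axis; each point is a cluster. Purple points are the 4888 clusters with opposite signs and green points the 2963 with the same sign.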

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

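The ratios under other scalings, in whole-count clusters and with library trends removed and the count of splits for same-direction calls were tests chosen after the data had been seen. The difference between the responses to 600 and to 1500 µmol photons m⁻² s⁻¹ stood out: 4888 clusters were called in opposite directions against LL, which all but fixes that each also passed the direct test of HL against ML, and they outnumbered same-direction calls 1.65 to 1. The lowest ratio under 3 other scalings was 1.41 (95% interval 1.35 to 1.48, library totals alone), it was 1.34 (1.28 to 1.41) with limma on log2(FPKM + 0.1), 2.62 (2.47 to 2.79) among clusters with whole counts in all 9 libraries, and 1.50 (1.43 to 1.57) with each library's trend on abundance and length removed. These values argue against scaling, library-wide abundance or length trends and, as far as non-whole counts mark them, reads divided among similar clusters as the whole cause. Over all clusters the log2 fold changes covaried positively (0.313), and in the upper 2 abundance quintiles negatively (−0.066). The simulated values of 0.0394 and 0.0039 leave out the sampling error of the shared LL libraries. A response of the alga that differs between moderate and strong light, a harvest at different times or phases of the light cycle and an exchange of labels between whole groups all stay open as untested, since the labels give no time from the shift to the harvest and no named gene could check the groups.

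Other groupings of the libraries were counted beside each test. For each pair of groups only 10 splits of 6 libraries exist, too few for a share below 0.05; the real split gave 15317, 12587 and 20219 calls for HL against LL, ML against LL and HL against ML, and the highest of the others 2, 1 and 1. In each case 1 of 10 splits, the real one, reached the real count. Over 100 splits of the 9 libraries, the joint test gave 21424 calls for the real split and 8897 for the highest other. Clusters moving the same way at both steps numbered 700 (highest other 0) and opposite calls 4888 (highest other 1). For each, 1 of 100 splits reached the real count. Splits that mix the groups widen the spread, most gave 0 joint calls, and whole groups were never exchanged. For the joint test a chance arrangement of these libraries could be excluded, so the libraries differ by group. Chance differences between cultures could not be, since no label says that the libraries of a group came from separate cultures. The counts for both steps and for opposite calls follow from the difference by group and decide nothing about graded or opposite patterns. For same-direction calls 3 of 100 splits, the real one included, reached the real 2963, and the highest of the others gave 8151. The other 2, with 4613 and 8151 same-direction calls and 5646 and 8897 joint calls, each kept 1 of the 3 groups whole. Other splits that did so gave 155, 0, 162 and 137 same-direction calls, so a whole group does not by itself account for the high counts.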

How the results depend on the processing

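Of 150 alternative values of the main counts, 137 stayed within 1.5 times the reported count and 13 were lower. This rule compares sizes and cannot register a reversal, and the balance of directions did turn in all 3 comparisons. For ML against LL this is given above. With DESeq2, 8192 clusters were higher and 7771 lower for HL against LL, where the main fit gave 7608 and 7709. For HL against ML, RLE factors gave 10215 higher and 10044 lower, where the main fit gave 9935 and 10284. All 249 alternatives for the named clusters and abundance shares kept their direction, with 0.00796 the highest adjusted p of a named cluster. The named clusters were picked for small p, so their stability does not extend to others. For the share of the 1000 most abundant clusters, ML minus LL was only −0.24 percentage points (exact two-sided permutation p = 0.8). The whole-count, trend-removed and overlap alternatives were chosen after seeing the data. With only whole-count clusters, fewer clusters were tested (13548) and 8950, 7412 and 10792 were called for HL against LL, ML against LL and HL against ML, 11566 jointly, 406 in the same direction at both steps and 1426 in the same direction against LL; the called shares were higher, at 66.1%, 54.7% and 79.7%. A minimum CPM of 5 in 3 libraries left 16757 clusters and 13157 calls for HL against ML. At least 2-fold changes numbered 6122, 4164 and 11884, and edgeR's test against a 1.5-fold minimum gave 5366, 3487 and 12181, both stricter by construction. Leaving out each library in turn gave 12821 to 14786, 10316 to 12438 and 18224 to 20282 calls, 19528 to 20599 jointly, 515 to 639 at both steps, 3705 to 4484 opposite and 2390 to 2626 in the same direction.

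Same-numbered libraries showed no shared deviation (correlations −0.04 to 0.01, others −0.01 to 0.04). That is no sign of pairing, but correlations over all tested clusters, many with few counts, could not exclude it. With a replicate block, 13792, 11180 and 19082 clusters were called, 19787 jointly, 586 at both steps, 4174 opposite and 2537 in the same direction; no named call changed. Gene list tests were not run for lack of gene names. Fewer rare clusters were called: 12.7% of the lowest abundance quintile passed in HL against LL, against 67.9% of the highest; the part that depth plays in this was not tested.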

Other observations

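The tests of depth by thinning and of Poisson sampling, and the sets counted for LL and HL, were chosen after the results they measure were seen. More clusters were detected in ML than in the other groups. At least 1 read was counted for 57160 ± 930 clusters in ML, 52937 ± 806 in LL and 52425 ± 424 in HL (SD, n = 3 each, exact two-sided permutation p = 0.1 for ML against each). After thinning to equal totals HL minus LL was −872 clusters (exact two-sided permutation p = 0.3), and −756 for clusters with at least 10 counts, where all HL libraries lay below all LL libraries (p = 0.1, exact, the smallest possible). A set of 3525 clusters was at least 8 times higher in ML than in both other groups, and 3102 of these had no count outside ML. Among the tested clusters, only 247 were called at least 8-fold higher in ML than in LL. The rule for the set had no minimum count, so that 1 read in ML and none elsewhere met it. By the same rule LL had a set of 1329 clusters, 1242 without a count elsewhere, and HL a set of 1851, 1623 without a count elsewhere. The ML set took 0.103% to 0.133% of the counts in the ML libraries.

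After thinning to equal totals, the lowest ML library still exceeded the highest of the other 6 by 2791 clusters, which argues against depth. The gap was 2827 without the 1000 most abundant clusters, which argues against room freed by abundant transcripts, and 1167 without the clusters at least 8 times higher in ML, so that a separate ML set is not the whole of it. Without the sets of all 3 groups the gap was 1789. Low-level background, such as residual DNA or unspliced RNA, and a broader expression of rare genes at 600 µmol photons m⁻² s⁻¹ both stay open and were not tested.

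Some clusters were present in 1 library of a group with at least 30 counts and had none in the other 2. There were 272 such cases in LL, 331 in ML and 275 in HL, over 777 clusters. Poisson sampling at the group means gives 1.07e-05 cases, but the minimum of 30 counts fixes a value near 0, so it decides nothing. Of the 777 clusters 93.1% held non-whole counts, against 63.8% of 3801 clusters of like abundance, an odds ratio of 7.59 (95% interval 5.71 to 10.3, Fisher's exact test), so a candidate explanation is that the counting program assigned reads of near-identical sequences to different clusters in different libraries. The joint test covered 527 of them and called 30.

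Clusters with whole counts were called more often at every abundance. In the lowest quintile 34.5% of whole-count and 18.7% of other clusters passed the joint test, in the middle quintile 82.4% and 59.5%, and in the highest 91.3% and 89.3%.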
